A study of Sus scrofa with 9 samples.

How the data were processed

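The samples were spleens of Ningxiang pigs, a Chinese fatty breed, at postnatal days 30, 90 and 210, with 3 libraries per age by the sample names. Per the labels' protocols total RNA was extracted with Trizol, RNA with an integrity number above 7 was used, and paired-end libraries were made. The labels name selection with oligo-dT beads but also a fraction without poly(A), a NovaSeq in the protocol but a HiSeq in the design text, and adipose tissue in a protocol of a spleen series, and these points were left as they stand. Selection of poly(A) RNA would leave few circRNAs and would lower histone messages, so both were read with that in mind. Per the submitters' processing notes reads were aligned with HISAT2 2.0, assembled into loci with StringTie 1.3.0, and Bowtie 0.12.2 was also used. The notes name the build mm8, a mouse build, although coordinates and names in the deposited tables are those of a pig assembly, so the build of the coordinates is not certain. The strand of the libraries, the counting tool and the circRNA caller are not given in the labels. No reference genome was held, so sequences were not analysed.

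The authors' gene table held read counts and FPKM per locus for the 9 libraries, and counts were used for tests and FPKM for levels. The authors' circRNA table held back-splice junction read counts and a signal in SRPBM, by the labels junction reads scaled by mapped reads. In the values it was the junction reads times 1 factor per library. The mapped reads implied by this factor were 48.3 to 57.2 M per library, which in day 30 replicate 1 and day 210 replicate 1 (48.3 and 48.7 M) was below the counts in genes (61.3 and 62.1 M), so that what the factor holds is open. Of 28095 loci 16335 carried 1 informative name, 350 merged several names, 10632 had no description and 3106 had no strand. Descriptions were turned into symbols through pairs fixed in advance, which matched 742 of 1030 list symbols, and loci with the same description were counted separately.

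The comparisons, gene lists and most alternatives were fixed before the data were examined. The plan named limma on log2 values, and edgeR replaced it because the table held raw counts, with limma kept as an alternative. Loci with a mean of at least 1 FPKM (19264) were fitted by edgeR quasi-likelihood (QL) with TMM factors (0.937 to 1.073) and a mean for each of the 3 ages, and tests were two-sided. Adjusted p is Benjamini-Hochberg (BH) over all loci tested in a comparison, with a threshold of 0.05. The standard error of a log2 change was taken as its size over the square root of F. The common biological coefficient of variation was 27.3%. Where the counts of an age summed to 0, the change is a lower bound with 3 counts put in the place of 0, and for sums of 1 to 3 counts a ratio with a 95% counting interval is given. No library was a copy of another, as the chi-square between counts of replicates had a median of 5.04 to 14.7 per gene and a mean of 89.6 to 293.

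Gene lists covered cell types (B cells, germinal centre, plasma cells, T cells, γδ T cells, cytotoxic and NK cells, red pulp macrophages, dendritic cells, neutrophils, mast cells, erythroid cells, megakaryocytes, endothelium, smooth muscle, fibroblasts and matrix, stromal chemokines). They also covered programmes (proliferation, histones, interferon, class I and class II presentation, pattern recognition, complement, cytokines, immediate early, heat shock, glucocorticoid, unfolded protein response, circadian clock, ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol, iron, V(D)J recombination, fetal growth) and contaminants or checks (adipocytes, pancreas, liver, skeletal muscle, neurons, mitochondrially encoded and sex-linked genes). Of 43 lists the 35 with at least 5 measured genes were tested by camera with a preset correlation of 0.01, BH over those lists, and again by camera with an estimated correlation and by fry. Since genes of a list move together between animals, the test with a preset correlation is the more lenient one, and the value with an estimated correlation is given beside each call. Values by fry are given for part of the lists. Members of a list that passed were counted over all genes and adjusted over the list alone.

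Named genes were, per comparison, the 8 largest increases and 8 largest decreases among loci past the threshold with an informative name and with all libraries of one age above those of the other. To these were added up to 4 members of each list with the smallest unadjusted p, and a fixed panel of cell type genes from MKI67 to XIST, of which HBB and XIST were not matched. For circRNAs the 4 largest changes each way and the 5 highest means were named. The text gives values for part of the genes so named, and others are not reported here. Loci whose description is shared by other loci, or which merge several descriptions, were treated as uncertain.

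Of 18908 circRNAs the 2748 seen in at least 4 of 9 libraries, with 69% of all junction reads, were tested by edgeR QL on junction reads with BH. Numbers detected were compared by the exact permutation of a one-way F over the assignments of 9 libraries to ages. Host and circRNA changes were compared by Spearman correlation with 1e+05 resamples.

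A self-test used simulated counts, drawn at random from the mean and dispersion of each of 19264 loci, each locus independently. Of these loci 200 were changed at day 90 by a known factor. At 2-fold 7% were recovered between days 30 and 90 and 13% between days 90 and 210, and at 4-fold 92% and 89.5%, with 11 and 8 unchanged loci also called. Among 2748 circRNAs 0% were recovered at 2-fold and 8.5% at 4-fold, so a circRNA that did not pass may still have changed severalfold. Of lists 3 of 3 were recovered, with 1 of 29 others called at 2-fold and 0 of 29 at 4-fold. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8), and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.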

Results

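Spleens of Ningxiang pigs were sampled at postnatal days 30, 90 and 210, with 3 libraries per age, and the deposited tables held read counts and FPKM per gene locus and back-splice junction reads per circular RNA (circRNA). Counted reads per library were 61.3, 59.2 and 57.4 M at day 30, 60.3, 55.8 and 52.0 M at day 90, and 62.1, 50.0 and 48.9 M at day 210. Junction reads numbered 12037, 11878 and 12252 at day 30, 15469, 15302 and 12232 at day 90, and 15397, 11434 and 10962 at day 210. Nothing in the labels beyond the sample names says that the libraries come from separate animals, so the p-values measure only the spread between these samples. Sex was not labelled. The comparisons ask which genes and circRNAs differ between the ages. Of 28095 loci 17463 (62.2%) carried a protein description, and 19264 with a mean of at least 1 FPKM were tested.

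Between any of the ages 1471 of 19264 loci changed with an adjusted p under 0.05, which was 7.6% of those tested, and 595 of them had no protein description. Leaving out 1 library moved this count to 601 without day 30 replicate 1, 493 without day 30 replicate 2, 692, 650 and 788 without day 90 replicates 1, 2 and 3, and 852 without day 210 replicate 2. The first principal component held 24.4% of the variance and placed day 30 libraries at −62.6, −63.1 and −39.3, day 90 libraries at 27.7, 15.3 and 13.1, and day 210 libraries at 18.2, 49 and 41.8. Libraries of the same age correlated at 0.935 to 0.944 and those of different ages at 0.905 to 0.943. A locus without description on chromosome 10 (MSTRG.13356, 10217 to 64404) took 7.02% and 7.01% of the counts in day 90 replicates 2 and 3. Where a named gene lost its call with a library left out, the highest adjusted p of the 9 left-out values is given with its library. In what follows the value after ± is the standard error for a log2 change and the standard deviation of 3 libraries for a mean FPKM. The deposited FPKM were not rescaled by TMM, so ratios of mean FPKM differ somewhat from the fitted changes.

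From day 30 to day 90, 15 of 22 erythroid and 7 of 10 platelet genes fell, and 12 of 17 B cell and 6 of 11 plasma cell genes rose. The erythroid and platelet lists had adjusted p = 0.048 and 0.0298 with an estimated correlation, while the B cell and plasma cell lists lost their calls, with adjusted p = 0.0976 and 0.173 with an estimated correlation. ANK1, which anchors the red cell membrane skeleton, fell by 5.41 ± 0.52 log2 units (adjusted p = 0.00586), from 7.25 ± 4.67 to 0.143 ± 0.0405 FPKM (n = 3 per age). TAL1, a transcription factor of erythroid and megakaryocyte precursors, fell by 2.94 ± 0.3 (adjusted p = 0.00586), from 5.45 ± 1.77 to 0.601 ± 0.0805 FPKM. MS4A1, the B cell surface protein CD20, rose by 1.32 ± 0.21 (adjusted p = 0.0122), from 6.45 ± 2.17 to 13.8 ± 1.22 FPKM.

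Of 22 measured erythroid genes 15 fell over all genes and 21 fell with p adjusted over the list alone, with a median of −3.04. SLC4A1, the anion exchanger band 3, fell by 4.9 ± 0.55 (adjusted p = 0.00598; MSTRG.15431, chromosome 12, 47465161 to 47481749), and CA1, the red cell carbonic anhydrase, by 6.55 ± 0.73 (adjusted p = 0.00586; MSTRG.5589, chromosome 4, 37728601 to 37737718). The Rh-associated glycoprotein RHAG fell by 6.05 ± 0.89 (adjusted p = 0.0105; MSTRG.10950, chromosome 7, 107897937 to 107923426). The erythroid regulator KLF1 fell by 6.21 ± 1.12 (adjusted p = 0.0172), and its call was lost without 3 of the 9 libraries in turn, with the highest adjusted p, 0.0625, without day 90 replicate 1. Its change was −11.07 without day 90 replicate 2, as the other day 90 libraries had 0 counts. Neither ALAS2, the first enzyme of haem synthesis (−1.41 ± 0.56, adjusted p = 0.174), nor the alpha globin HBA1 (−1.15, adjusted p = 0.24) passed. The list was lower by the camera test (adjusted p = 2.96e-38, and adjusted p = 0.048 with an estimated correlation). ANK1 lies at MSTRG.19935 on chromosome 17, 9927185 to 10072776, and TAL1 at MSTRG.7753 on chromosome 6, 5320962 to 5339510.

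Of 10 measured megakaryocyte and platelet genes 7 fell over all genes and 8 adjusted over the list alone, with a median of −1.62. TREML1, a receptor of platelet granules, fell by 2.57 ± 0.28 (adjusted p = 0.00586; MSTRG.11066, chromosome 7, 115304372 to 115309178). GP1BA, the platelet receptor for von Willebrand factor, fell by 2.18 ± 0.27 (adjusted p = 0.00782; MSTRG.14813, chromosome 12, 15031896 to 15033800). ITGA2B, the platelet integrin chain, fell by 1.57 ± 0.2 (adjusted p = 0.00782), and VWF itself by 1.79 ± 0.19 (adjusted p = 0.00586), from 20.1 ± 4.04 to 5.01 ± 0.148 FPKM. The list test gave an adjusted p of 1.86e-19, and adjusted p = 0.0298 with an estimated correlation.

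Neutrophil granule genes were lower by the list test (adjusted p = 0.000368, median −1.13, 9 measured), with adjusted p = 0.154 with an estimated correlation. Of these 9, 2 fell over all genes and 5 adjusted over the list alone. S100A12, a calcium-binding protein of granulocytes, had 0 counts at day 90 against 108 at day 30 and was at least 33.1-fold lower (adjusted p = 0.0227). This call was lost without 4 of the 9 libraries in turn, with adjusted p = 0.0695 without day 90 replicate 1. S100A9 fell by 1.9 ± 0.48 (adjusted p = 0.0499), but 8 of the 9 left-out libraries removed its call, with adjusted p = 0.144 without day 90 replicate 2. Of the antimicrobial peptides of pig granules, protegrin-2 fell by 5.5 ± 1.04 (adjusted p = 0.0197) and a protegrin-3-like locus by 6.74 ± 1.25 (adjusted p = 0.0188), with 0.0678 and 0.0658 without day 90 replicate 2. The latter had −11 (adjusted p = 0.0573) without day 90 replicate 1, as the other day 90 libraries had 0 counts. LTF, the granule lactoferrin, did not pass (−2.75 ± 0.78, adjusted p = 0.0693), nor did S100A8 (−1.97 ± 0.64, adjusted p = 0.105).

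Of 17 measured B cell genes 12 rose over all genes, and 15 rose and 1 fell adjusted over the list alone, with a median of 0.81. CD79B, a chain of the antigen receptor, rose by 0.84 ± 0.11 (adjusted p = 0.00818), from 27.8 ± 2.01 to 43.5 ± 5.43 FPKM (MSTRG.15540, chromosome 12, 52292469 to 52295345). VPREB3, a protein of B cell development, rose by 1.59 ± 0.29 (adjusted p = 0.017), and 0.0573 without day 90 replicate 1. The list test gave an adjusted p of 1.52e-13, and adjusted p = 0.0976 with an estimated correlation. MS4A1 lies at MSTRG.3221 on chromosome 2, 149517972 to 149531450.

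Of 8 germinal centre genes 4 rose over all genes and 6 adjusted over the list alone, with a median of 0.75 (adjusted p = 7.26e-08, and adjusted p = 0.0976 with an estimated correlation). MYBL1, a transcription factor of dividing germinal centre cells, rose by 1.59 ± 0.24 (adjusted p = 0.0109), from 1.08 ± 0.074 to 2.86 ± 0.643 FPKM. Of 11 plasma cell genes 6 rose over all genes and 8 adjusted over the list alone, with a median of 0.63 (adjusted p = 1.32e-07, and adjusted p = 0.173 with an estimated correlation). JCHAIN, which joins the chains of secreted IgA and IgM, rose by 1.28 ± 0.24 (adjusted p = 0.0187), from 440 ± 38.3 to 922 ± 274 FPKM, with adjusted p = 0.0562 without day 30 replicate 2. SDC1, the plasma cell marker CD138, rose by 1.14 ± 0.19 (adjusted p = 0.0135), and PRDM1, the regulator of plasma cell fate, by 0.63 ± 0.12 (adjusted p = 0.0188), with 0.0541 without day 90 replicate 1 and 0.0676 without day 90 replicate 3. An immunoglobulin gamma-chain locus on an unplaced scaffold rose by 2.95 ± 0.73 (adjusted p = 0.0487), with 0.123 without day 90 replicate 1, and which gamma gene it holds is uncertain.

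T cell genes were higher by the list test at day 90, with 19 of 21 members positive, a median of 0.43 and an adjusted p of 0.000281, but 0 members passed singly and the list had adjusted p = 0.406 with an estimated correlation. CD3E, a chain of the T cell receptor complex, had 0.27 ± 0.13 (adjusted p = 0.247), and CD8A 0.77 ± 0.43 (adjusted p = 0.321). Genes of cytotoxic and NK cells had a median of 0.38 over 15 members, 0 of which passed (adjusted p = 0.0153, and adjusted p = 0.232 with an estimated correlation). This call was lost without day 30 replicate 3 (adjusted p = 0.102). KLRD1, a receptor of NK cells, had 1.54 ± 0.45 (adjusted p = 0.0787), and the granule protease GZMB had −0.51 ± 0.68 (adjusted p = 0.705). TIGIT, a checkpoint receptor described in the table as a T-cell immunoreceptor, rose by 1.67 ± 0.3 (adjusted p = 0.0172; MSTRG.16763), with 0.0576 without day 30 replicate 2.

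Of 13 endothelial and sinus lining genes 9 fell over all genes and 13 adjusted over the list alone (median −0.98, adjusted p = 1.49e-15, and adjusted p = 0.0407 with an estimated correlation). CLEC14A, a lectin of vessel walls, fell by 1.18 ± 0.14 (adjusted p = 0.00782; MSTRG.10730), FLT1, a VEGF receptor, by 1.04 ± 0.15 (adjusted p = 0.00867), and TEK, the angiopoietin receptor, by 0.9 ± 0.14 (adjusted p = 0.0123; MSTRG.341). Of 23 genes of fibroblasts and extracellular matrix 14 fell over all genes and 21 adjusted over the list alone (median −0.99, adjusted p = 7.5e-21, and adjusted p = 0.104 with an estimated correlation). COL5A2, a fibrillar collagen chain, fell by 1.17 ± 0.12 (adjusted p = 0.00586; MSTRG.19025), from 24.6 ± 2.53 to 9.56 ± 1.18 FPKM, and FBLN2, a basement membrane protein, by 1.03 ± 0.12 (adjusted p = 0.00782; MSTRG.16202). COL1A1, the main chain of collagen I, fell by 1.62 ± 0.4 (adjusted p = 0.0453; MSTRG.15276), with adjusted p = 0.143 without day 90 replicate 1 and its call lost without 6 of the 9 libraries in turn. SERPINH1 of the heat shock list, the collagen chaperone, fell by 1.17 ± 0.21 (adjusted p = 0.0171), with 0.0609 without day 90 replicate 3.

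Of 11 smooth muscle and capsule genes 2 fell over all genes and 4 adjusted over the list alone (median −0.61, adjusted p = 0.000615, and adjusted p = 0.375 with an estimated correlation). The actin regulator CALD1 was one of them (−0.59 ± 0.13, adjusted p = 0.03, and 0.109 without day 30 replicate 2). Of 14 stromal chemokine genes 3 fell over all genes, and 2 rose and 7 fell adjusted over the list alone (median −0.36, adjusted p = 0.0364, and adjusted p = 0.173 with an estimated correlation). CCL21, which draws T cells into the white pulp, fell by 0.79 ± 0.18 (adjusted p = 0.0373), with 0.136 without day 90 replicate 1, and CXCL12, a niche chemokine, by 0.63 ± 0.11 (adjusted p = 0.0161), with 0.066 without day 90 replicate 1. The list call was lost without day 30 replicates 2 and 3 (adjusted p = 0.111 and 0.0665) and day 90 replicates 1 and 3 (0.0543 and 0.0675). Of 11 fetal growth genes 4 fell over all genes and 5 adjusted over the list alone (median −0.41, adjusted p = 0.000151, and adjusted p = 0.048 with an estimated correlation). GRB10, an imprinted brake on growth signals, fell by 0.8 ± 0.12 (adjusted p = 0.0109), and IGF1, the insulin-like growth factor, by 3.25 ± 0.56 (adjusted p = 0.0154), with 0.0594 without day 90 replicate 2.

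Interferon-stimulated genes were lower at day 90 by the list test (24 measured, median −0.72, adjusted p = 9.1e-06, and adjusted p = 0.461 with an estimated correlation), but 0 members passed. ISG15, a ubiquitin-like antiviral protein, had −2.42 ± 0.69 (adjusted p = 0.0727), with 94.7, 108 and 13.1 FPKM in the day 30 libraries. The MX1/MX2 locus, which merges the descriptions of both genes and so is of uncertain identity, had −1.61 ± 0.51 (adjusted p = 0.0986). The mean of the list deviated by 1.24 and 1.35 in day 30 replicates 1 and 2 and by −0.3 in replicate 3.

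At day 90 immediate early genes had a median of −0.31, with 3 of 25 falling over all genes and 4 adjusted over the list alone (adjusted p = 0.00971, and adjusted p = 0.406 with an estimated correlation). However, adjusted p was 0.156 without day 30 replicate 2. EGR1, a transcription factor induced within minutes of a stimulus, fell by 0.68 ± 0.15 (adjusted p = 0.0342), and 0.128 without day 90 replicate 1. Glucocorticoid-responsive genes had a median of −0.44, with 0 of 11 past over all genes and 5 falling adjusted over the list alone (adjusted p = 0.00845, and adjusted p = 0.406 with an estimated correlation), and 0.051 without day 30 replicate 2. Heat shock genes had a median of −0.11, with 2 of 15 falling over all genes and 4 adjusted over the list alone (adjusted p = 0.049, and adjusted p = 0.476 with an estimated correlation). That adjusted p was 0.208 without day 30 replicate 2, 0.19 without day 90 replicate 2 and 0.057 without day 90 replicate 3. Iron handling genes had a median of −0.32, with 2 of 18 falling over all genes and 5 adjusted over the list alone (adjusted p = 0.00459, and adjusted p = 0.0976 with an estimated correlation). BLVRA, which reduces biliverdin from haem, fell by 0.71 ± 0.14 (adjusted p = 0.022), and 0.0808 without day 90 replicate 2.

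The remaining lists did not pass at day 90. Red pulp macrophage genes had a median of −0.18 over 17 members (adjusted p = 0.525), with CD163, the haemoglobin scavenger receptor, at −0.3 ± 0.19 (adjusted p = 0.378) and the iron exporter SLC40A1 at an adjusted p of 0.769. Proliferation genes had a median of −0.15 over 47 members (adjusted p = 0.198), with MKI67 at −0.29 ± 0.34 (adjusted p = 0.671). The adjusted p was 0.254 for dendritic cells, in which CD1A rose by 1.35 ± 0.22 (adjusted p = 0.0128, and 0.05 without day 90 replicate 1). XCR1, the receptor of cross-presenting cells, fell by 1.3 ± 0.3 (adjusted p = 0.0353, and 0.114 without day 90 replicate 2). The lists of γδ T cells (0.0526), the unfolded protein response (0.0652), ribosomal proteins (0.0824), cytokines (0.148), replication-dependent histones (0.184) and the circadian clock (0.235) did not pass either. Nor did complement (0.246), oxidative phosphorylation (0.254), class II presentation (0.267), cholesterol synthesis (0.273), glycolysis (0.356) and pattern recognition receptors (0.573). Class I presentation (0.834) and V(D)J recombination (0.356) did not pass, and in each the median, −0.05 and 0.05, had the opposite sign to the test.

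In all 1171 of 19264 loci changed from day 30 to day 90 (6.1%), of which 396 rose and 775 fell, with 4454 at an unadjusted p under 0.05. The share that rose was 33.8%, but 21.8% with limma on TPM and 127 of 1720 loci with limma on log2(FPKM + 1), where the median shift of all genes was −0.148. The count was 473 without day 30 replicate 1, 383 without day 30 replicate 2, and 280, 327 and 473 without day 90 replicates 1, 2 and 3. Of 69 named genes past the test 25 stayed past with any library left out, among them ANK1, TAL1, CA1, GP1BA, VWF, COL5A2, CD79B and MS4A1. Without 1 library some list medians moved by over 1.5 times with the call kept. Neutrophil genes had −0.75 without day 90 replicate 1, interferon-stimulated genes −1.08 without day 90 replicate 3 and fetal growth genes −0.65 without day 90 replicate 2. Glucocorticoid-responsive genes had −0.68 without day 30 replicate 3 and heat shock genes −0.17 without day 30 replicate 1. The erythroid median was −1.75 with limma after quantile scaling and −1.97 with limma on log2(FPKM + 1). Without day 30 replicate 1 ANK1 had −4.75, SLC4A1 −4.26 and RHAG −5.41, and RHAG had −7.02 without day 90 replicate 2. The glycoprotein GP2, known from pancreatic granules and M cells, also kept its call and rose by 2.88 ± 0.39 (adjusted p = 0.00826; MSTRG.5041).

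**Figure D1:**
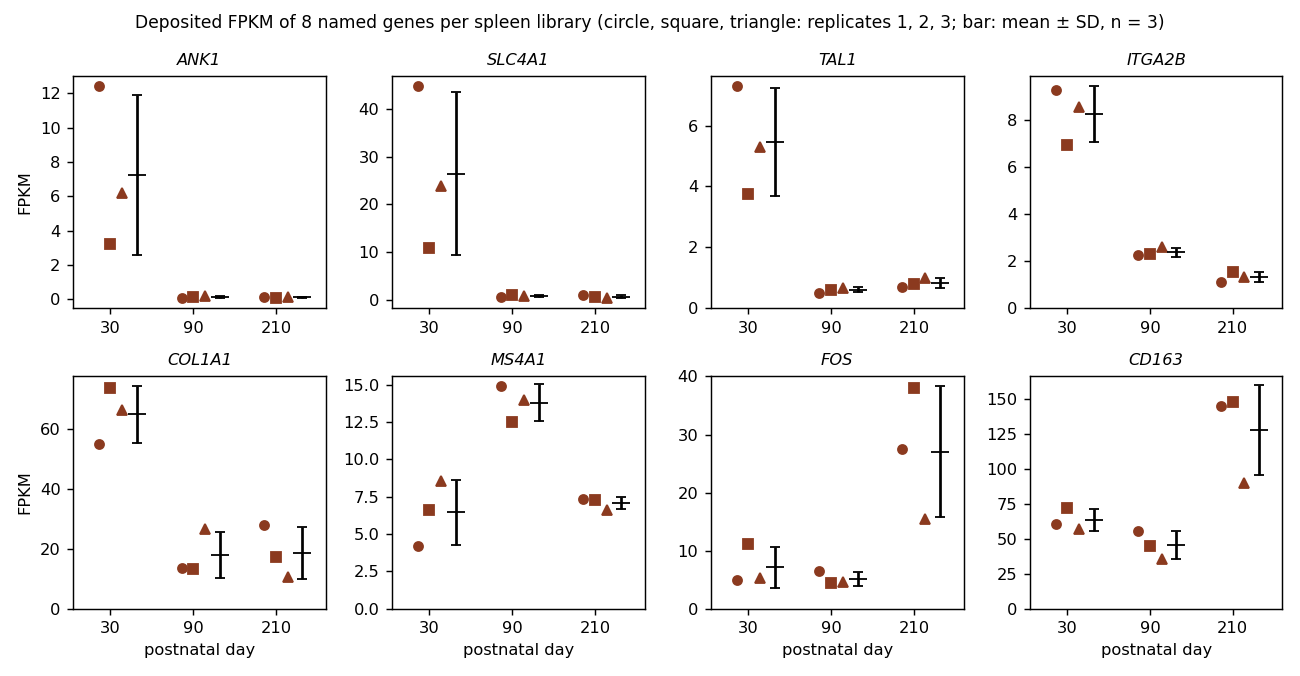
Deposited FPKM (vertical axes, linear) of ANK1, SLC4A1, TAL1, ITGA2B, COL1A1, MS4A1, FOS and CD163 against postnatal day, with 1 marker per spleen library and a bar for mean ± SD (n = 3). ANK1 lay at 7.25 ± 4.67 at day 30 and 0.143 ± 0.0405 at day 90, and CD163 rose to 128 ± 32.4 at day 210.

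From day 90 to day 210, 2 of 17 B cell genes fell, and 5 of 25 immediate early genes and 3 of 17 red pulp macrophage genes rose. These lists were called with the preset correlation and lost their calls at adjusted p = 0.0911, 0.0654 and 0.43 with an estimated correlation. By fry the B cell and immediate early lists were called (adjusted p = 0.0103 and 0.00798), and the red pulp macrophage list was not (adjusted p = 0.191). CD79B fell 2.34-fold (−1.22 ± 0.11, adjusted p = 0.0071), from 43.5 ± 5.43 to 20.6 ± 1.33 FPKM (n = 3 per age). FOS, a transcription factor that follows acute stimulation, rose 4.76-fold (2.25 ± 0.39, adjusted p = 0.0479; MSTRG.10340, chromosome 7, 53506450 to 53508913), from 5.11 ± 1.18 to 27 ± 11.3 FPKM. CD163 rose by 1.34 ± 0.19 (adjusted p = 0.0272; MSTRG.7649, chromosome 5, 107612555 to 107646713), from 45.5 ± 10.2 to 128 ± 32.4 FPKM. Of 25 named genes past this test 1, CD79B, stayed past with any library left out, and 24 lost their calls without day 90 replicate 3, where adjusted p was 0.118 for CD163 and 0.11 for an immunoglobulin E (IgE) locus. FOS had an adjusted p of 0.178 without day 90 replicate 2.

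Of 17 B cell genes 2 fell over all genes, and 13 fell and 1 rose adjusted over the list alone, with a median of −0.83. CD72, an inhibitory receptor of B cells, fell by 0.93 ± 0.14 (adjusted p = 0.0312), with 0.139 without day 90 replicate 2. MS4A1 had −1.12 ± 0.21 (adjusted p = 0.0568). The list test gave an adjusted p of 3.4e-15, and adjusted p = 0.0911 with an estimated correlation. CLEC17A, a lectin of germinal centre B cells, fell by 0.97 ± 0.15 (adjusted p = 0.0338), with 0.141 without day 90 replicate 2. The germinal centre list had a median of −0.43, with 0 of 8 past over all genes and 3 falling adjusted over the list alone (adjusted p = 0.000952, and adjusted p = 0.262 with an estimated correlation). The plasma cell list did not pass (median 0.01, adjusted p = 0.725), with JCHAIN at 0.03 ± 0.23 (adjusted p = 0.972).

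Of 12 class II presentation genes 1 fell over all genes, and 7 fell and 1 rose adjusted over the list alone (median −0.51, adjusted p = 2.72e-05, and adjusted p = 0.0625 with an estimated correlation). CD40, the costimulatory receptor of antigen-presenting cells, fell by 0.65 ± 0.11 (adjusted p = 0.0415), with 0.147 without day 90 replicate 2. Class I genes had a median of −0.24, with 0 of 10 past over all genes and 3 falling adjusted over the list alone (adjusted p = 0.0243, and adjusted p = 0.494 with an estimated correlation). They lost the call without day 90 replicate 1 (0.375) and day 210 replicate 2 (0.271). Dendritic cell genes had a median of −0.31, with 1 of 10 falling over all genes and 2 adjusted over the list alone (adjusted p = 0.000276, and adjusted p = 0.0654 with an estimated correlation). CD1A, which presents lipids, fell by 1.35 ± 0.22 (adjusted p = 0.0415), with 0.133 without day 90 replicate 3.

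Of 25 immediate early genes 5 rose over all genes and 13 adjusted over the list alone (median 0.5, adjusted p = 3.4e-15, and adjusted p = 0.0654 with an estimated correlation). NR4A1, an orphan receptor induced by antigen receptor signals, rose by 1.73 ± 0.21 (adjusted p = 0.0201; MSTRG.6653), and FOSB 10.6-fold (3.41 ± 0.53, adjusted p = 0.04; MSTRG.9082), with 0.0957 and 0.144 without day 90 replicate 2. Of 11 glucocorticoid-responsive genes 2 rose over all genes (DUSP1 and CD163, also in other lists) and 9 adjusted over the list alone. The median was 0.9 (adjusted p = 3.78e-12, and 0.0887 with an estimated correlation). DUSP1, the phosphatase of stress kinases, rose by 1.42 ± 0.16 (adjusted p = 0.0188; MSTRG.19567), from 8.17 ± 0.44 to 24.6 ± 4.89 FPKM, with 0.0758 without day 90 replicate 3. DDIT4, an inhibitor of mTORC1, had 1.11 ± 0.22 (adjusted p = 0.0713). Heat shock genes had a median of 0.24, with 0 of 15 past over all genes and 2 rising adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.43 with an estimated correlation). Its adjusted p was 0.0795 without day 90 replicate 2 and 0.166 without day 210 replicate 1. The circadian clock list had a median of 0.2 with 0 of 14 past (adjusted p = 0.0243, and adjusted p = 0.166 with an estimated correlation), and 0.0594 and 0.0738 without day 210 replicates 2 and 3.

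Of 17 red pulp macrophage genes 3 rose over all genes, and 3 rose and 1 fell adjusted over the list alone (median 0.16, adjusted p = 0.011, and adjusted p = 0.43 with an estimated correlation). The adjusted p was 0.0605 without day 90 replicate 1 and 0.104 without day 210 replicate 1. SLC11A1, a metal transporter of phagosomes, rose by 1.71 ± 0.19 (adjusted p = 0.0188; MSTRG.19233), and MERTK, a receptor for dying cells, by 0.74 ± 0.12 (adjusted p = 0.0415; MSTRG.4567), with 0.0782 and 0.152 without day 90 replicate 3. SLC40A1 had 0.28 ± 0.25 (adjusted p = 0.69). Of 18 iron handling genes 2 rose over all genes and 6 adjusted over the list alone (median 0.34, adjusted p = 7.32e-06, and adjusted p = 0.0625 with an estimated correlation). The metal transporter SLC11A2 had 0.69 ± 0.15 (adjusted p = 0.0796). Neutrophil genes had a median of 0.47, with 0 of 9 past over all genes, and 4 rising and 2 falling adjusted over the list alone (adjusted p = 0.0025, and adjusted p = 0.19 with an estimated correlation). S100A12 had 127 counts at day 210 against 0 at day 90 and was at least 42.9-fold higher, with an adjusted p of 0.0579.

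An immunoglobulin E epsilon chain locus rose 32.7-fold (5.03 ± 0.66, adjusted p = 0.0231; MSTRG.22035, Scaffold1483, 18542 to 37740), from 0.0816 ± 0.0197 to 3.08 ± 1.42 FPKM. PF4, the platelet chemokine, fell by 1.73 ± 0.23 (adjusted p = 0.0231), with 0.1 without day 90 replicate 3. Heparan sulfate glucosamine 3-O-sulfotransferase 2, which modifies heparan chains, fell by 3.03 ± 0.37 (adjusted p = 0.0203), with 0.0957 without day 90 replicate 2. CDKN1A, described as cyclin-dependent kinase inhibitor 1, rose by 1.6 ± 0.26 (adjusted p = 0.0415), with 0.144 without day 90 replicate 2. The megakaryocyte list had a median of −0.37, with 0 of 10 past over all genes and 3 falling adjusted over the list alone (adjusted p = 0.000163, and adjusted p = 0.166 with an estimated correlation). Without day 90 replicate 3 this median was −0.19. GP1BA had −1.57 ± 0.28 (adjusted p = 0.0531). The erythroid list had a median of −0.43 with 0 of 22 past (adjusted p = 0.0471, and adjusted p = 0.599 with an estimated correlation). It lost its call without day 30 replicate 3 (0.0532), day 90 replicates 2 and 3 (0.592 and 0.0657) and day 210 replicates 2 and 3 (0.271 and 0.148).

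Proliferation genes were lower by the list test (47 measured, median −0.33, adjusted p = 2.72e-05, and adjusted p = 0.559 with an estimated correlation). Without day 210 replicate 2 the median was −0.03, the test pointed the other way and the adjusted p was 0.889. Its list mean deviated by −1.17 in that library, against 0.18 and 0 in the other day 210 libraries. Of these genes 1 rose over all genes, namely MCM5, a subunit of the replicative helicase (0.97 ± 0.13, adjusted p = 0.0238, and 0.11 without day 90 replicate 3), and it was also the 1 past the test adjusted over the list alone. Replication-dependent histones had a median of −0.32 with 0 of 7 past (adjusted p = 0.0243, and adjusted p = 0.532 with an estimated correlation), and 0.06 (adjusted p = 0.883) without day 210 replicate 2. Ribosomal proteins had a median of −0.34, with 2 of 57 falling over all genes and 5 adjusted over the list alone (adjusted p = 1.05e-13, and adjusted p = 0.343 with an estimated correlation). One of these was RPL12 of the large subunit (−0.88 ± 0.15, adjusted p = 0.0429, and 0.139 without day 90 replicate 2). Oxidative phosphorylation had a median of −0.17 with 0 of 44 past (adjusted p = 0.00612, and adjusted p = 0.575 with an estimated correlation), and 0.216 and 0.0678 without day 210 replicates 2 and 3. Interferon-stimulated genes had a median of −0.75 with 0 of 24 past (adjusted p = 1.6e-06, and adjusted p = 0.434 with an estimated correlation), and −0.39 without day 90 replicate 3, whose list mean was 0.44 against −0.38 and −0.23 in the other day 90 libraries. Stromal chemokines had a median of −0.35 with 0 of 14 past over all genes, and 2 rising and 5 falling adjusted over the list alone (adjusted p = 0.0332, and adjusted p = 0.19 with an estimated correlation). This call ended at 0.0795, 0.086 and 0.0687 without day 90 replicate 2, day 210 replicate 1 and day 210 replicate 2.

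The other lists did not pass between day 90 and day 210. T cell genes had a median of 0.2 (adjusted p = 0.0622), γδ T cells 0.26 (0.129), endothelium 0.15 (0.143) and smooth muscle 0.27 (0.194). COL1A1 had −0.17 ± 0.39 (adjusted p = 0.893), and the matrix list an adjusted p of 0.997 with a median of −0.1 against a test pointing up. Cytotoxic and NK cell genes (0.142, median 0.01) and the unfolded protein response (0.989, median 0.02) likewise had a test pointing down. The adjusted p was 0.0528 for V(D)J recombination, 0.104 for pattern recognition receptors, 0.109 for cholesterol synthesis and for fetal growth, 0.261 for complement, 0.475 for cytokines and 0.621 for glycolysis. INSIG1, which holds back sterol synthesis, rose by 0.98 ± 0.17 (adjusted p = 0.0451), with 0.169 without day 90 replicate 3.

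In all 103 of 19264 loci changed from day 90 to day 210 (0.5%), of which 67 rose and 36 fell, with 2717 at an unadjusted p under 0.05. The share that rose was 65%, but 36.4% without day 90 replicate 1, where 11 loci remained, and 88.5% with limma on log2(FPKM + 1), where the median shift of all genes was 0.108. The count was 61 without day 30 replicate 2, 11, 7 and 7 without day 90 replicates 1, 2 and 3, and 32 and 35 without day 210 replicates 1 and 2. List medians that moved by over 1.5 times with the call kept were those of red pulp macrophages (0.25, 0.06 and 0.26 without day 90 replicate 2 and day 210 replicates 2 and 3) and neutrophils (0.79 and 0.76 without day 90 replicate 2 and day 210 replicate 2). Without day 210 replicate 1 the medians were −0.61 for proliferation, −0.4 for class I, −0.28 for oxidative phosphorylation and −0.71 for histones. Stromal chemokines had −0.23 without day 90 replicate 1.

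**Figure D2:**
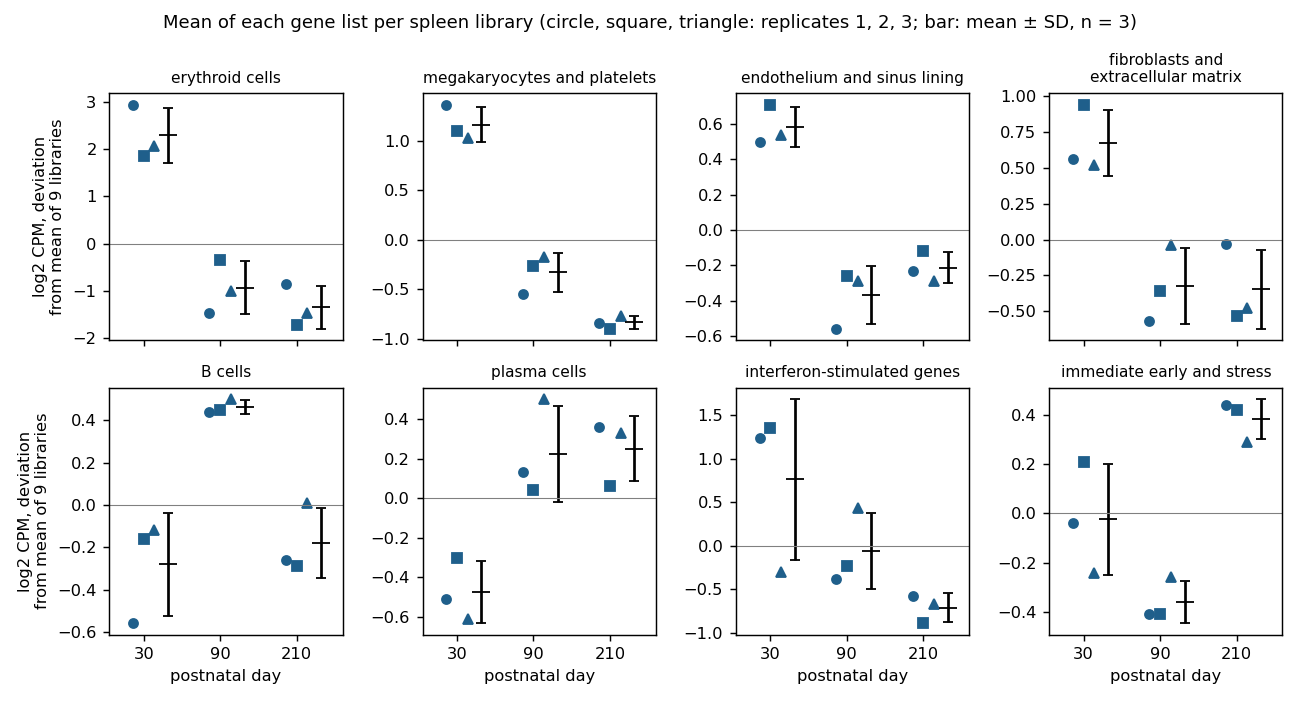
Mean of 8 gene lists in each spleen library, as log2 CPM relative to the mean of the 9 libraries, against postnatal day, with a marker per library and a bar for mean ± SD (n = 3). Erythroid genes stood at 2.94, 1.86 and 2.06 at day 30 and below 0 in all older libraries, and interferon-stimulated genes were high in day 30 replicates 1 and 2 (1.24 and 1.35) but not in replicate 3 (−0.3).

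From day 30 to day 210, 21 of 22 erythroid, 7 of 10 platelet and 13 of 24 interferon-stimulated genes fell, and 4 of 21 T cell and 5 of 11 plasma cell genes rose. The erythroid and platelet lists had adjusted p = 0.0417 and 0.0151 with an estimated correlation, while the interferon, T cell and plasma cell lists lost their calls, with adjusted p = 0.245, 0.245 and 0.167 with an estimated correlation. ANK1 fell by 5.85 ± 0.54 log2 units (adjusted p = 0.00234), to 0.12 ± 0.00843 FPKM (n = 3 per age). TREML1 fell by 4.11 ± 0.3 (adjusted p = 0.000937), from 8.25 ± 0.526 to 0.454 ± 0.18 FPKM. CD3E rose by 0.76 ± 0.13 (adjusted p = 0.0143; MSTRG.12898, chromosome 9, 93750601 to 93765729), from 20 ± 1.25 to 32.7 ± 3.15 FPKM, with 0.0547 without day 30 replicate 2. SLC11A1 rose by 1.62 ± 0.19 (adjusted p = 0.00495), from 9.11 ± 1.66 to 27.3 ± 3.56 FPKM.

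Of 22 erythroid genes 21 fell over all genes and 22 adjusted over the list alone, with a median of −3.88 (adjusted p = 4.17e-44, and adjusted p = 0.0417 with an estimated correlation). HEMGN, a nuclear protein of blood precursors, fell by 3.88 ± 0.44 (adjusted p = 0.00406; MSTRG.92), and the erythroid membrane-associated protein by 5.2 ± 0.49 (adjusted p = 0.00234; MSTRG.7672). ALAS2 fell by 2.54 ± 0.59 (adjusted p = 0.0379), from 36 ± 11.6 to 6.11 ± 4.12 FPKM, with 0.108 without day 30 replicate 2. HBZ, the embryonic alpha-like globin, fell by 4.13 ± 0.77 (adjusted p = 0.0194), with 0.061 without day 30 replicate 2. Of 10 megakaryocyte genes 7 fell over all genes and 8 adjusted over the list alone, with a median of −2.23 (adjusted p = 1.21e-29, and adjusted p = 0.0151 with an estimated correlation). ITGA2B fell by 2.58 ± 0.21 (adjusted p = 0.00124; MSTRG.15430) and GP1BA by 3.75 ± 0.3 (adjusted p = 0.00116). A locus described as multidrug resistance-associated protein 4-like, a name carried by 9 loci and so of uncertain identity, fell by 7.1 ± 0.58 (adjusted p = 0.00124; MSTRG.14419).

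Of 24 interferon-stimulated genes 13 fell over all genes and 21 adjusted over the list alone, with a median of −1.5 (adjusted p = 9.64e-16, and adjusted p = 0.245 with an estimated correlation). ISG15 fell by 3.71 ± 0.74 (adjusted p = 0.0237; MSTRG.8712), from 72 ± 51.5 to 5.43 ± 0.872 FPKM, and IFIT1, which binds viral RNA, by 2.5 ± 0.52 (adjusted p = 0.0266; MSTRG.18125). The MX1/MX2 locus fell by 2.51 ± 0.53 (adjusted p = 0.0289; MSTRG.17051), with 84, 90.6 and 21.9 FPKM in the day 30 libraries. Without day 210 replicate 2 the adjusted p was 0.0847 for ISG15, 0.0927 for IFIT1 and 0.0956 for MX1/MX2, and each lost its call without 5 of the 9 libraries in turn.

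Of 21 T cell genes 4 rose over all genes, and 9 rose and 1 fell adjusted over the list alone (median 0.72, adjusted p = 3.59e-07, and adjusted p = 0.245 with an estimated correlation). THEMIS, a regulator of T cell selection, rose by 1.21 ± 0.14 (adjusted p = 0.00418; MSTRG.1411), and CD3D by 0.72 ± 0.15 (adjusted p = 0.0247), with 0.0944 without day 30 replicate 2. The TRAC locus rose by 1.07 ± 0.22 (adjusted p = 0.0247; MSTRG.10609), with 0.0835 without day 30 replicate 2, and as it merges several descriptions its identity is uncertain. Of 5 γδ T cell genes 3 rose over all genes and adjusted over the list alone (median 0.6, adjusted p = 0.00149, and adjusted p = 0.0862 with an estimated correlation). CCR9, a gut-homing receptor, rose by 0.88 ± 0.14 (adjusted p = 0.0113), and TRDC, the δ chain constant region, by 0.6 ± 0.14 (adjusted p = 0.04), with 0.124 without day 30 replicate 1. CD8A had 1.08 ± 0.43 (adjusted p = 0.169). The cytotoxic list did not pass (median 0.24, adjusted p = 0.212), although GZMK rose by 1.99 ± 0.48 (adjusted p = 0.0426, and 0.111 without day 30 replicate 2), and GZMB had 0.07 ± 0.67 (adjusted p = 0.969).

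Of 11 plasma cell genes 5 rose over all genes and 7 adjusted over the list alone (median 0.7, adjusted p = 6.36e-08, and adjusted p = 0.167 with an estimated correlation). SDC1 rose by 1.47 ± 0.19 (adjusted p = 0.00581; MSTRG.3923), PRDM1 by 1.04 ± 0.12 (adjusted p = 0.00408; MSTRG.1256) and JCHAIN by 1.32 ± 0.24 (adjusted p = 0.0179; MSTRG.11745), the last with 0.0542 without day 30 replicate 2. The IgE locus rose 15.7-fold (3.97 ± 0.62, adjusted p = 0.0109), with 3.46 to 4.92 log2 units when 1 library was left out. An IgG heavy chain locus rose by 2.98 ± 0.57 (adjusted p = 0.0212; MSTRG.22272, Scaffold1928, 230 to 26874), with 0.0818 without day 30 replicate 2 and a rise of 2.01 without day 210 replicate 3. The germinal centre list had a median of 0.38, with 0 of 8 past over all genes and 3 rising adjusted over the list alone (adjusted p = 0.00953, and adjusted p = 0.349 with an estimated correlation). It was lost without day 210 replicate 3 (0.108). The B cell list did not pass (median 0.08, adjusted p = 0.349), with MS4A1 at 0.19 ± 0.21 (adjusted p = 0.62), although FCRL1, a receptor of B cells, rose by 1.89 ± 0.22 (adjusted p = 0.00406; MSTRG.5906).

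Of 13 endothelial genes 7 fell over all genes and 12 adjusted over the list alone (median −0.83, adjusted p = 6.26e-11, and adjusted p = 0.0417 with an estimated correlation). CLDN5, a tight junction protein, was among them (−1.02 ± 0.16, adjusted p = 0.0109; MSTRG.17402). Of 23 matrix genes 15 fell over all genes and 20 adjusted over the list alone (median −0.95, adjusted p = 6.36e-20, and adjusted p = 0.113 with an estimated correlation). COL5A2 had −1.41 ± 0.12 (adjusted p = 0.00177). COL1A1 fell by 1.79 ± 0.4 (adjusted p = 0.0335), with 0.104 without day 30 replicate 2. Of 14 stromal chemokine genes 3 fell over all genes and 6 adjusted over the list alone (median −0.39, adjusted p = 0.000115, and adjusted p = 0.0417 with an estimated correlation). Among these was CCL19, which guides cells to T zones (−1.46 ± 0.19, adjusted p = 0.00594; MSTRG.13951). Of 11 fetal growth genes 6 fell over all genes and adjusted over the list alone (median −0.67, adjusted p = 6.93e-07, and adjusted p = 0.0265 with an estimated correlation). Among them was IGF2BP2, an RNA-binding protein of growth (−2.22 ± 0.39, adjusted p = 0.017, and 0.0513 without day 30 replicate 2). Smooth muscle genes had a median of −0.42 with 0 of 11 past (adjusted p = 0.0208, and adjusted p = 0.533 with an estimated correlation). That p became 0.082, 0.051 and 0.156 without day 30 replicate 2, day 210 replicate 2 and day 210 replicate 3.

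Of 10 dendritic cell genes 3 fell over all genes and 5 adjusted over the list alone (median −0.52, adjusted p = 7.52e-05, and adjusted p = 0.0417 with an estimated correlation). FLT3, the growth receptor of dendritic cells, fell by 1.54 ± 0.23 (adjusted p = 0.00961; MSTRG.14137), and XCR1 by 1.7 ± 0.3 (adjusted p = 0.0166; MSTRG.15758), with 0.0562 without day 210 replicate 2. Of 12 class II genes 1 rose and 3 fell over all genes, and 1 rose and 5 fell adjusted over the list alone (median −0.19, adjusted p = 0.0328, and adjusted p = 0.179 with an estimated correlation). SLA-DMB, a peptide loader, fell by 0.59 ± 0.11 (adjusted p = 0.0224), with 0.0777 without day 30 replicate 1. The class II call was lost without day 30 replicates 1 and 2 (0.0703 and 0.0722) and day 210 replicates 1 and 3 (0.0691 and 0.0637). Complement had a median of −0.23, with 3 of 20 falling over all genes and 4 adjusted over the list alone (adjusted p = 0.0403, and adjusted p = 0.533 with an estimated correlation). The complement call ended at 0.224 and 0.0775 without day 30 replicates 1 and 2 and at 0.0537 and 0.168 without day 210 replicates 2 and 3. Cytokines had a median of −0.3, with 1 of 21, TNF (−0.93 ± 0.2, adjusted p = 0.0326, and 0.104 without day 30 replicate 2), falling over all genes and adjusted over the list alone (adjusted p = 0.0372, and adjusted p = 0.167 with an estimated correlation). The cytokine call was lost without day 30 replicates 1 and 2 (0.0918 and 0.0805) and day 210 replicates 2 and 3 (0.0537 and 0.0669).

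Of 25 immediate early genes 5 rose and 1 fell over all genes, and 6 rose and 1 fell adjusted over the list alone (median 0.32, adjusted p = 0.000491, and adjusted p = 0.257 with an estimated correlation). FOS rose by 1.94 ± 0.39 (adjusted p = 0.0242), with 0.0784 without day 30 replicate 1, and DUSP1 by 1.24 ± 0.16 (adjusted p = 0.00581). Of 11 glucocorticoid-responsive genes 3 rose over all genes and adjusted over the list alone (median 0.17, adjusted p = 0.0105, and adjusted p = 0.405 with an estimated correlation). Without day 30 replicate 3 its median was −0.11 (adjusted p = 0.422) and without day 210 replicate 1 adjusted p was 0.0695. DDIT4 rose by 1.19 ± 0.22 (adjusted p = 0.0195), with 0.0671 without day 30 replicate 1. The red pulp macrophage list did not pass (adjusted p = 0.152), with 4 members rising, 1 falling and a median of −0.07 against a test pointing up. CD163 rose by 1.04 ± 0.19 (adjusted p = 0.0177), with 0.0614 without day 30 replicate 1, and SLC40A1 had 0.13 ± 0.25 (adjusted p = 0.803).

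Proliferation genes had a median of −0.48 with 1 of 47 rising over all genes and 0 past adjusted over the list alone (adjusted p = 3e-06, and adjusted p = 0.542 with an estimated correlation), and 0.051 without day 210 replicate 2. MKI67 had −0.56 ± 0.34 (adjusted p = 0.358). Histones had a median of −0.77 with 0 of 7 past (adjusted p = 0.00144, and adjusted p = 0.405 with an estimated correlation). This median was −0.36 without day 210 replicate 2 and −1.17 without day 210 replicate 1, and the list means of the day 210 libraries were 0.17, −1.5 and −0.12. Ribosomal proteins had a median of −0.28 (0.02 with limma after quantile scaling) with 1 of 57 falling over all genes and adjusted over the list alone (adjusted p = 0.000115, and adjusted p = 0.542 with an estimated correlation). Oxidative phosphorylation had −0.25 with 0 of 44 past (adjusted p = 0.000748, and adjusted p = 0.542 with an estimated correlation). V(D)J recombination had a median of −0.3, with 2 of 6 falling over all genes and adjusted over the list alone (adjusted p = 0.0152, and adjusted p = 0.245 with an estimated correlation), and 0.0806 without day 30 replicate 2. Of these 6 genes CD34 of vessels and blood precursors fell by 1.15 ± 0.14 (adjusted p = 0.0051; MSTRG.12221). The remaining lists did not pass, with adjusted p of 0.0663 for pattern recognition receptors and for the unfolded protein response, 0.107 for class I, 0.196 for glycolysis and 0.285 for neutrophils. Iron handling (0.514), the circadian clock (0.58), cholesterol synthesis (0.847) and heat shock (0.976) did not pass either. In iron handling 2 genes rose and 3 fell, among the latter the transferrin receptor TFRC (−1.18 ± 0.28, adjusted p = 0.0427, and 0.113 without day 30 replicate 1).

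In all 1203 of 19264 loci changed from day 30 to day 210 (6.2%), of which 491 rose and 712 fell, with 4570 at an unadjusted p under 0.05. The share that rose was 40.8%, but 22.9% with limma on log2(FPKM + 1) and 29.5% with limma on TPM. The count was 419 without day 30 replicate 1, 342 without day 30 replicate 2, 799 without day 90 replicate 2 and 392 without day 210 replicate 2. Of 86 named genes past the test 33 stayed past with any library left out, among them ANK1, TREML1, VWF, COL5A2, FLT3, THEMIS, SDC1, DUSP1 and SLC11A1. List medians that moved by over 1.5 times with the call kept were those of T cells (0.42 without day 210 replicate 3), germinal centre genes (0.59 and 0.68 without day 30 replicate 2 and day 210 replicate 1) and ribosomal proteins (−0.14 without day 30 replicate 2). Without day 210 replicate 1 smooth muscle genes had −0.75, proliferation genes −0.78 and immediate early genes 0.2, the last also 0.16 without day 30 replicate 3. Glucocorticoid-responsive genes had 0.43 without day 30 replicate 1 and 0.11 without day 210 replicate 3. The V(D)J list ran from −0.52 to −0.07 over the left-out libraries. The erythroid median was −2.55 with limma after quantile scaling and −2.57 with limma on log2(FPKM + 1). Among genes ANK1 had −5.2 and the multidrug resistance-associated protein 4-like locus −6.48 without day 30 replicate 1, and ALAS2 had −3.13 and HBZ −4.75 without day 210 replicate 1.

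Lists with fewer than 5 measured genes were not tested. The highest mean in each was KIT at 9.71 FPKM for mast cells and basophils, PNPLA2 at 9.46 for adipocytes, AMY2 at 1.22 for exocrine pancreas and APOA1 at 31 for liver. It was CASQ1 at 7.2 for skeletal muscle and STMN2 at 21.6 for neurons and glia, while 0 genes of the mitochondrially encoded and sex-linked lists were measured.

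The table held 18908 circRNAs from 5066 host genes, of which 16383 were exonic, 1002 intronic and 1523 lay between genes. Of all circRNAs 11929 (63.1%) were seen in 1 library, 402 in all 9, and 8070 had 1 junction read in total. Detected circRNAs per library numbered 4098 ± 122 at day 30, 4557 ± 482 at day 90 and 4043 ± 725 at day 210 (n = 3 each, exact p = 0.496), and the p was 0.0857 without day 210 replicate 1. Per M mapped reads as implied by the signal this came to 81 ± 3.73, 81.26 ± 10.2 and 81.02 ± 16.8 (exact permutation p = 1). Junction reads numbered 12060 ± 188, 14330 ± 1820 and 12600 ± 2440 (exact permutation p = 0.421), or 238.3 ± 9.67, 255.6 ± 36.6 and 252.5 ± 55.7 per M such reads (exact p = 0.846). The highest mean signal belonged to circRNA3565 between genes on chromosome 16 (6520 ± 1790, 5560 ± 1630 and 5910 ± 1260 SRPBM, adjusted p = 0.988 from day 30 to day 90). Another, circRNA641 from exportin-4, a nuclear transport receptor, had 2120 ± 275, 1980 ± 304 and 1770 ± 281 SRPBM (adjusted p = 0.988).

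Of 2748 circRNAs seen in at least 4 of 9 libraries 12 changed between any ages, and the tested ones had a median of 15 reads in all. With DESeq2, and with edgeR on circRNAs seen in at least 7 of 9 libraries, 0 changed in any test. From day 30 to day 90, 3 rose and 2 fell. The circRNA of 4 exons of the diaphanous homolog 2 gene, a regulator of actin and endosomes (circRNA12804, chromosome X, 80695596 to 80734373), had 0 reads at day 30 and 0, 7 and 18 at day 90. This was at least 7.4-fold higher (adjusted p = 0.00101), but without day 90 replicate 3 the adjusted p was 0.583. Its host locus had −0.35 ± 0.35 (adjusted p = 0.604). Between genes circRNA3375 rose by 3.35 ± 0.57 (adjusted p = 5.95e-06), with 10, 0 and 0 reads at day 30 and 66, 59 and 0 at day 90. Without day 30 replicate 1, which held all reads of that age, its size was not measured. Another, circRNA3477, rose by 2.32 ± 0.58 (adjusted p = 0.0394), and its call was lost without day 30 replicates 2 and 3 (0.86 and 0.127) and day 90 replicates 1 and 2 (0.193 and 0.256). Also between genes circRNA3306 fell from 17, 24 and 13 reads to 0, at least 20.3-fold (adjusted p = 1.81e-08), and circRNA3352 from 7, 15 and 11 to 0, at least 12.4-fold (adjusted p = 0.000114).

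From day 90 to day 210, 2 circRNAs rose and 3 fell. The intron circRNA ciRNA145 of an uncharacterized gene on chromosome 10 (1913538 to 1919786) had 0, 0 and 163 reads at day 90 and 2, 0 and 0 at day 210. It was 76.5-fold lower (95% interval 20.8 to 637, adjusted p = 1.16e-12). Without day 90 replicate 3, which held all reads of that age, the call was lost (adjusted p = 0.916). Between genes circRNA3306 was at least 5.33-fold higher (adjusted p = 0.0085), but its 0, 0 and 15 reads at day 210 came from replicate 3 alone, without which both ages were at 0 and it was not tested. Its adjusted p was 0.0893, 0.0945 and 0.127 without day 90 replicates 1, 2 and 3. A further one, circRNA3363, rose by 2.8 ± 0.53 (adjusted p = 0.000179), with 0.061, 0.0862 and 0.613 without day 90 replicates 1 and 2 and day 210 replicate 3. Its reads were 0, 0 and 18 at day 90 and 18, 21 and 80 at day 210. Its change was 1.64 without day 210 replicate 3 and had no measured size without day 90 replicate 3. Likewise circRNA3443 was at least 6.57-fold lower (adjusted p = 0.002), but its 21 reads at day 90 came from replicate 3 alone, without which it was not tested. The same bound held for circRNA3435 (adjusted p = 0.00492), lost without day 90 replicate 1 (0.344) and day 210 replicate 1 (0.071). The count of 5 was 3, 3 and 2 without day 90 replicates 1, 2 and 3, and 3 without day 210 replicate 3.

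From day 30 to day 210, 5 circRNAs rose and 4 fell. The intron circRNA ciRNA145 fell 237-fold (95% interval 65.3 to 1960, adjusted p = 2.78e-20), from 147, 161 and 141 reads to 2, 0 and 0, and kept its call with any library left out. Of the circRNAs of the same region, circRNA3443 was at least 16.6-fold lower (adjusted p = 2.02e-07) and the intron circRNA ciRNA147 at least 9.86-fold lower (adjusted p = 0.00442), the latter lost without day 30 replicate 2 (0.15) and day 210 replicate 1 (0.0562). Elsewhere on chromosome 10 circRNA3435 was at least 13.7-fold lower (adjusted p = 4.34e-06). The diaphanous homolog 2 circRNA was at least 11-fold higher (adjusted p = 3.16e-05), with 14, 14 and 7 reads at day 210, while its host locus had 0.1 ± 0.35 (adjusted p = 0.892). Between genes circRNA10726 was at least 9.78-fold higher (adjusted p = 0.00144), with 0.901 without day 210 replicate 2. Likewise circRNA10751 was at least 7.57-fold higher (adjusted p = 0.0103), with 0.0687, 0.0956 and 0.123 without day 30 replicates 1, 2 and 3 and 0.0771 and 0.21 without day 210 replicates 1 and 2. For circRNA3375 the rise of 2.44 ± 0.59 (adjusted p = 0.0103) had 0.763, 0.627 and 0.283 without day 30 replicates 2 and 3 and day 210 replicate 2. The last, like day 30 replicate 1, held all reads of its age. The other increase, picked out after its values were seen, was circRNA3363 with 2.3 (adjusted p = 0.00313). Its reads were 9, 9 and 6 at day 30 and 18, 21 and 80 at day 210, and this comparison was not run with a library left out.

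Changes of circRNAs followed those of their host genes weakly across 2123 hosts, with Spearman correlations of 0.228 from day 30 to day 90, 0.123 from day 90 to day 210 and 0.191 from day 30 to day 210 (permutation p = 1e-05, the smallest that 1e+05 resamples can give). Genes are not independent, so the p-values say little beyond the sign.

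**Figure D3:**
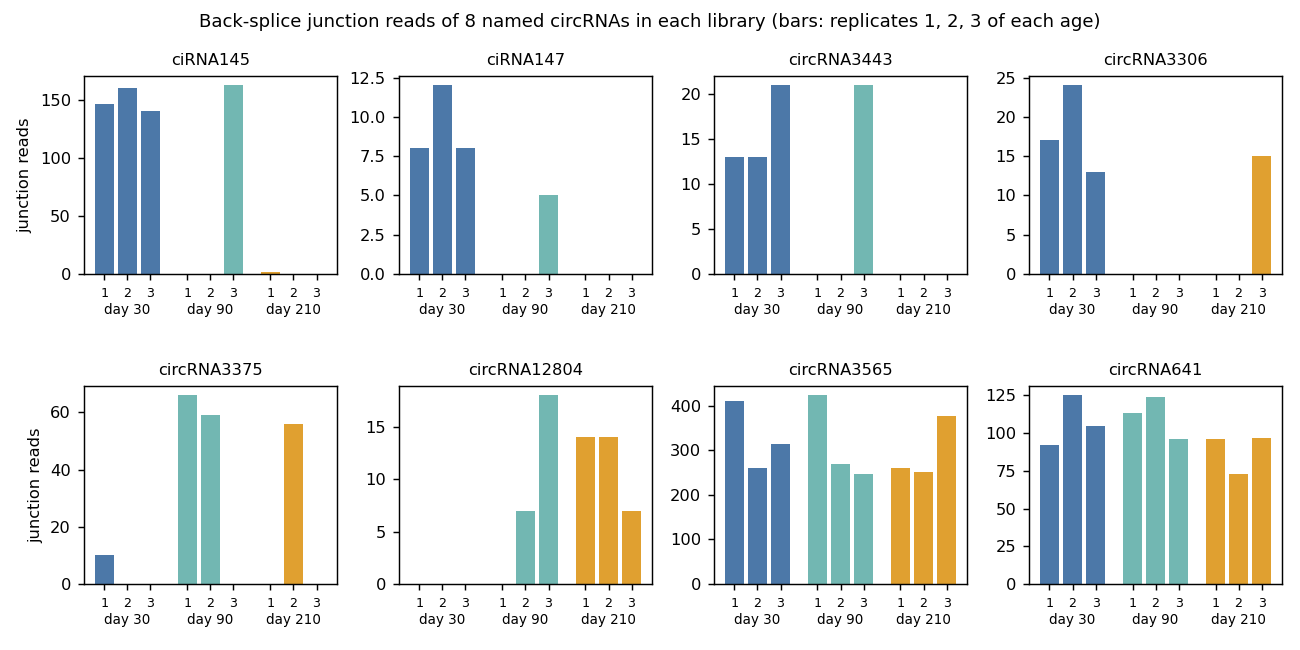
Back-splice junction reads (vertical axes, linear from 0) of 8 named circRNAs, with a bar per spleen library and colours for the 3 ages. The intron circRNA ciRNA145 had 147, 161 and 141 reads at day 30 and, at day 90, 163 in replicate 3 against 0 in the others.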

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

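DESeq2, limma on log2(FPKM + 1) and on SRPBM, the 10 highest loci left out, described loci alone, and library sizes or detection per mapped reads were chosen after the results were seen, and the other settings were planned. Over the settings that leave out no library, 2493 values of single genes kept their direction and side of the threshold, 325 were no longer past it, 20 came past it and 7 turned. DESeq2 called 3324 genes between any ages, 2424 from day 30 to 90, 801 from day 90 to 210 and 2300 from day 30 to 210, and held 99.8 to 100% of the edgeR calls. With limma a pseudocount of 0.1 gave 770 genes from day 30 to 210 and a pseudocount of 5 gave 1760 from day 30 to 90. TPM with limma gave 914 genes between any ages, 710 from day 30 to 90 and 755 from day 30 to 210. Robust fitting gave 160 genes from day 90 to 210, and no filter gave 66. A filter of 5 FPKM gave 548, 404, 58 and 494 genes between any ages and in the comparisons of days 30 and 90, 90 and 210, and 30 and 210. Asking for a log2 change of at least 1 left 446, 59 and 547 genes in these comparisons, and fitting the 6 libraries of a comparison alone gave 1490, 73 and 499, for a cause that was not tested. Among lists an estimated correlation left 4, 0 and 6 calls, and fry gave 9 from day 90 to 210 and 14 from day 30 to 210. Medians of called lists moved by over 1.5 times with the call kept in 6, 11 and 4 lists with limma on log2(FPKM + 1), 6, 10 and 0 at a pseudocount of 0.1, 2, 2 and 4 with limma after quantile scaling, and 0, 1 and 4 without a filter. Leaving out the 10 highest loci kept 98.8 to 99.9% of the calls.

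COL1A1 from day 90 to 210 turned to 0.03 with limma at each pseudocount (1, 0.1 and 5), and GZMB from day 30 to 210 turned to −0.02, −0.13 and −0.06 with limma at pseudocounts of 1 and 0.1 and on TPM. SLC40A1 from day 30 to 210 was 0 at a pseudocount of 0.1. With limma after quantile scaling the median of the ribosomal list from day 30 to 210 was 0.02. None of these genes had passed the test.

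With replicate number as a block 651 genes changed between any ages, and 582, 43 and 531 in the comparisons of days 30 and 90, 90 and 210, and 30 and 210, with 3 circRNAs from day 90 to 210. Replicate numbers showed no sign of pairing, as correlations between libraries of the same number ran from −0.071 to 0.099 and 0 of 9 were above 0.1, and 1 library correlated best with its own number in both other ages.

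For circRNAs 10 times the pseudocount in limma gave 2 from day 90 to 210, and limma on SRPBM gave 3, with circRNA3602 at −0.81 from day 30 to 90. Asking for 2 of 9 libraries gave 21 between any ages and 12, 10 and 16 in the comparisons. Asking for 7 of 9 gave 0 with edgeR in all of them, with 40, 51, 47 and 49 at an unadjusted p under 0.05. DESeq2 also gave 0 throughout, with 39, 54, 38 and 61 at an unadjusted p under 0.05, against 12, 5, 5 and 9 with edgeR.

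With each library left out in turn, gene counts ran from 493 to 1671 between any ages, 280 to 1556 from day 30 to 90, 7 to 139 from day 90 to 210 and 342 to 1053 from day 30 to 210. Lists called ran from 16 to 22, 14 to 21 and 19 to 24. The counts of circRNAs ran from 9 to 13 between any ages, 4 to 8, 2 to 6 and 6 to 10. The p of circRNA detection ran from 0.0857 to 0.775. The direction turned for GZMB (−0.86 to 0.29 from day 30 to 90, −0.06 to 1.04 from day 90 to 210 and −0.57 to 0.86 from day 30 to 210), FOS from day 30 to 90 (−0.52 to 0.23), MS4A1 (−0.03 to 0.39), KLRD1 (−0.16 to 0.7) and SLC40A1 (−0.05 to 0.4) from day 30 to 210. It also turned for JCHAIN (−0.14 to 0.38), COL1A1 (−0.53 to 0.37) and MKI67 (−0.61 to 0.09) from day 90 to 210. None of these had passed. Among circRNAs it turned for circRNA3565 (−0.25 to 0.3 from day 90 to 210 and −0.5 to 0.03 from day 30 to 210), circRNA641 (−0.22 to 0.01 from day 30 to 90), circRNA3602 (−0.62 to 1.29 from day 90 to 210), ciRNA145 (−8.81 to 2.65 from day 90 to 210) and circRNA3375 (−4.89 to 7.34 from day 30 to 210). The proliferation median from day 90 to 210 ran from −0.61 to −0.03. Fewer samples remain when a library is left out, and beyond that the cause of these moves was not tested. Depth limits the circRNAs, with a median of 15 reads in all among those tested.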

Other observations

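The tests of erythroid genes, of immediate early genes and of all-or-none circRNAs were chosen after the results were seen, and the splits were planned. The test of the highest loci took the place of a first one that left them out and could not tell. Further genes moved with age. FBLN1, a matrix glycoprotein, fell by 2.21 ± 0.34 from day 30 to day 90 (edgeR QL, adjusted p = 0.0116, chromosome 5, 22021192 to 22109089), with 0.0517 without day 90 replicate 1. An SGLT1-like sodium and glucose cotransporter locus rose by 2.15 ± 0.22 (adjusted p = 0.00586, MSTRG.17317), from 0.586 ± 0.0746 to 2.3 ± 0.817 FPKM. Angiotensinogen, the precursor of angiotensin, rose by 1.78 ± 0.42 (adjusted p = 0.0394, MSTRG.17478), with 0.136 without day 30 replicate 2. IL33, an alarmin of stromal cells, fell by 1.27 ± 0.29 (adjusted p = 0.0385), with 0.0946 without day 90 replicate 2. CR1, a complement receptor, rose by 1.08 ± 0.22 (adjusted p = 0.0237), with 0.0776 without day 90 replicate 2.

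From day 90 to day 210 RGS1, a regulator of chemokine signals in lymphocytes, rose by 1.51 ± 0.26 (adjusted p = 0.0451), and CD200 receptor 2 by 1.73 ± 0.28 (adjusted p = 0.0415), with 0.16 without day 90 replicate 3 and 0.134 without day 90 replicate 2. Deoxyribonuclease gamma, which digests DNA of dying cells, fell by 1.07 ± 0.14 (adjusted p = 0.0231), and phospholipase D4, an exonuclease of dendritic and B cells, by 0.94 ± 0.13 (adjusted p = 0.0264), with 0.11 and 0.112 without day 90 replicate 3. From day 30 to day 210 the arginase ARG1 fell by 2.38 ± 0.49 (adjusted p = 0.0257), with 0.0864 without day 210 replicate 2, and laminin gamma-3 rose by 2.31 ± 0.52 (adjusted p = 0.034), with 0.111 without day 30 replicate 2.

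Erythroid and megakaryocyte genes were lower at days 90 and 210 than at day 30, and blood formation in the spleen of the young pig that later ends could account for it. If less blood left in the older tissue were the whole cause, globins, ALAS2 and AHSP should have fallen as much as the other erythroid genes. A first test on the fold changes of the members gave a difference of medians of −1.79 (exact permutation p = 0.232). A second test, chosen after that value was seen, took the other members minus these late ones per library and gave 1.17 for day 30 against the 6 older libraries (exact permutation p = 0.0952), so less blood was not excluded. A few loci taking most of the counts were excluded, since the share of the 10 highest loci could lower all others by at most −0.15 log2 units, against list medians of −3.04 and −1.62 at day 90 and −3.88 and −2.23 at day 210, while age and a changed share of other cells stay open.

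Immediate early and glucocorticoid-responsive genes were higher at day 210 than at day 90, and 1 library as the cause was excluded, as the highest adjusted p of both lists with any library left out was 1.18e-07 and each day 210 library lay above each day 90 library in the mean of each list (0.24 to 0.53 against −0.46 to −0.26). These p-values are those with the preset correlation. The lists, which share DUSP1, had adjusted p = 0.0654 and 0.0887 with an estimated correlation and 0.00798 and 0.0171 by fry. Handling at collection may have differed between the ages, which would move the same genes. The heat shock list, which handling might also move, had a median of 0.24 (adjusted p = 0.011, and 0.43 with an estimated correlation), which does not decide it. How each age was collected is not labelled and cannot be told apart from age.

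Of 12 circRNAs called changed 9 were all or none within an age, with 0 reads in one library and 10 or more in another. Altogether 90 circRNAs were of this kind, against at most 8 in 1000 simulated sets (median 2), but these sets hold counting error only, and few molecules copied in amplification cannot be told apart, as the tables do not say which reads are copies. Junctions that come from differences between the genomes of the animals could give this, and the share was 39.3% of circRNAs between genes (44 of 112) against 12.2% of exonic ones (38 of 311, Fisher exact p = 3.7e-09). Intron circRNAs had a share of 42.1% (8 of 19), so the pattern is not particular to the class between genes and stays a hypothesis. Neighbours such as ciRNA145, ciRNA147 and circRNA3443 are not independent, and this pattern replaced an idea on proliferation after the reads per library were seen.

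Of 280 possible splits of the libraries between any ages 100 were drawn, with the real one among them. The highest of the others drawn gave 493 genes and 10 circRNAs, against the real 1471 and 12, which only 1 of the 100, the real one, reached. Chance was excluded for genes at a share under 0.05. For circRNAs 12 against 10 leaves it open, and undrawn splits were not run. For pairs of ages 10 splits are too few for a share under 0.05. The real and highest other counts of genes were 1171 and 3 from day 30 to 90, 103 and 2 from day 90 to 210, and 1203 and 4 from day 30 to 210, each reached by 1 split. For lists they were 18 and 18 (2 splits), 20 and 14 (1) and 23 and 22 (1). For circRNAs they were 5 and 3 (1 split), 5 and 8 (3) and 9 and 3 (1).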
